A study of Mus musculus with 8 samples.

How the data were processed

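Bone marrow cells of C57BL/6 Csf1r-EGFP mice were sorted into a CD11b+ and a CD11b- population, both positive for F4/80 and VCAM1, with 4 biological replicates each, and SmartSeq2 libraries were sequenced, per the labels. Each library had a deposited file of whole-number counts per gene symbol, which its name calls FPKM. The authors also deposited a table of CPM over all 8 libraries, and each library's counts divided by their total and scaled as CPM gave it back with a largest difference of 0.0005. TopHat2, HTSeq 0.10.0, DESeq2 and the build mm9 are listed in the submitters' processing notes, with no role or order. The annotation, strand setting and treatment of multiply mapped reads are not given in the sources used here. SmartSeq2 does not mark strand, so reads of a gene and of an overlapping or antisense partner cannot be told apart. The p-values measure the spread between biological replicates, as the design text calls them.

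The files list 18817 rows. Of these 27, under 25 distinct names, carry numbers in place of gene symbols, as spreadsheet programs produce from symbols that look like dates. These rows held 0.205% to 0.514% of counts and were kept out of library totals and tests. No listed symbol has a hyphen. Of the fixed lists the 6 globin genes, 8 MHC class II genes, Ahsp, Epb42, Ighd, Ighm, Igha and Hspa1b were not analysed here, nor was Ly6g. The reporter transcript was not analysed here either. No coordinates are given, because the reference in use (GENCODE M21) is of another build. It served only for exon lengths by symbol, which 18088 of 18790 named genes had (96.3%).

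The main test was edgeR 4.0.16 in R 4.3.3 on the counts, with TMM scaling, the filterByExpr defaults (a minimum count of 10 and a minimum total of 15), the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, with no covariate. Fold changes are CD11b+ over CD11b- and were fitted with a prior count of 0.125. Standard errors were worked back from the quasi-likelihood F. Where a group had no count the fold is given as a bound against a floor of 3 counts over the pooled libraries of that group. Gene sets were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 1 and a preset correlation of 0.01, and with lists of at least 3 tested genes. List levels used log2(CPM + 1) and an exact permutation test. The analysis plan had assumed FPKM for the levels. As the files hold counts and CPM, CPM was used, and the alternatives set on FPKM and on reads recovered from CPM were not run, the latter because it would repeat the main test.

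The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 of 11965 genes changed. In that test 3 unchanged genes were called, the 1 list that was moved had a camera adjusted p of 1.1e-18 and none of 23 lists left unmoved was called. That simulation draws genes independently, and so does not show how camera behaves where genes of a list vary together between replicates.

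The named genes followed a rule fixed before the data were examined. It took the genes of the sort, the 8 genes with the highest and the 8 with the lowest fold among called genes whose libraries did not overlap and whose higher mean was at least 50 CPM, the 2 most abundant tested members of each list, where a list passed camera its member with the largest change in the list's direction, and members needed to show that a list moved both ways. Gene models without a standard symbol were skipped (19 higher and 25 lower). The rule named 82 genes, of which some, and some other list members, are not reported here. Heme synthesis genes and the other gene families of the closing section were chosen after the data were examined. The lists were resident macrophage, lysosome, monocyte, primary granule, neutrophil, eosinophil, basophil and mast cell, erythroid, megakaryocyte and platelet, B progenitor, mature B cell, plasma cell, T cell, NK cell, plasmacytoid dendritic cell, conventional dendritic cell, MHC class II, stem and progenitor, stroma, endothelium, cell cycle, iron and heme handling, type I interferon response, immediate early and endoplasmic reticulum secretory genes.

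Alternatives set before the data were examined were DESeq2 1.42.0 (81 genes had no adjusted p and were left out), RLE size factors, no filter, a CPM of at least 10 in 4 libraries, other prior counts and pseudocounts, library weights, the replicate number as a block, a minimum of 2-fold, camera with an estimated correlation, fry and leaving out each library. Added after seeing the data were limma on log2(CPM + 1), no scaling, no scaling with totals without the 20 most abundant genes, length-scaled counts, and leaving out the pair of CD11b- libraries highest in Mpo.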

Results

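RNA was sequenced from a pair of cell populations sorted from the femoral bone marrow of untreated C57BL/6 mice that carry a Csf1r-EGFP transgene, a reporter in which the Csf1r promoter, active in monocytes and macrophages, drives green fluorescent protein. Both sorts required the macrophage surface proteins F4/80 and VCAM1 together with the reporter. The population called CD11b+ here was positive for the myeloid integrin CD11b, negative for the neutrophil antigen Ly6G and low for the reporter. The population called CD11b- lacked CD11b. Each had 4 biological replicates, and libraries were made with SmartSeq2, a full-length cDNA protocol that starts from very little RNA. Total gene counts were 36604660 to 47951234 in the CD11b+ libraries and 27462607 to 35160747 in the CD11b- libraries. These include the rows that carry numbers in place of gene symbols, which were kept out of the totals used for tests and floors. A count of 0 allows up to 0.0627 to 0.110 CPM (counts scaled to library totals) in a single library. These floors, and the counting intervals below, cover counting error only, because the reads carry no molecular identifiers. Between 12695 and 13634 genes were detected in CD11b+ libraries and between 13010 and 13624 in CD11b- libraries. The 10 most abundant genes took 18.6% ± 0.411 of CD11b+ counts and 8.45% ± 0.635 of CD11b- counts (SD, n = 4). No replicate pair was alike within sampling noise, with chi-square over degrees of freedom from 130 to 229. The series title frames the comparison as whether sorts bearing macrophage surface proteins hold macrophages or other cells carrying macrophage fragments.

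The CD11b+ libraries were rich in transcripts of granulocyte granules, and the CD11b- libraries in transcripts of red cell precursors, proliferating cells and B cell precursors. Ngp, a neutrophil granule protein, stood at 62702 ± 11281 CPM in CD11b+ and 220 ± 211 CPM in CD11b- (SD, n = 4), and Mpo, the myeloperoxidase of primary granules, at 42479 ± 8180 and 2916 ± 2448 CPM. Car2, a carbonic anhydrase abundant in erythroid cells, stood at 370 ± 121 CPM in CD11b+ and 13037 ± 3039 CPM in CD11b-. Of 11965 genes tested, 1751 were higher and 1798 lower in CD11b+, together 3549 or 29.7%, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. A change of at least 2-fold was seen in 2843 of them, and a change of at least 16-fold in 336 higher and 321 lower genes. The 4 libraries of one population all lay above the 4 of the other in 36.5% of tested genes, against 2.86% by chance. On simulated counts with the spread of these libraries and 200 genes changed, the same test recovered 7% of genes changed 2-fold and 37% of genes changed 4-fold over 11965 genes. It called 53 genes there, against 3549 here, so the Benjamini-Hochberg cut-off was stricter in the simulation. These shares therefore do not measure the recovery of the main test. Genes that were not called could still differ.

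**Figure D1:**
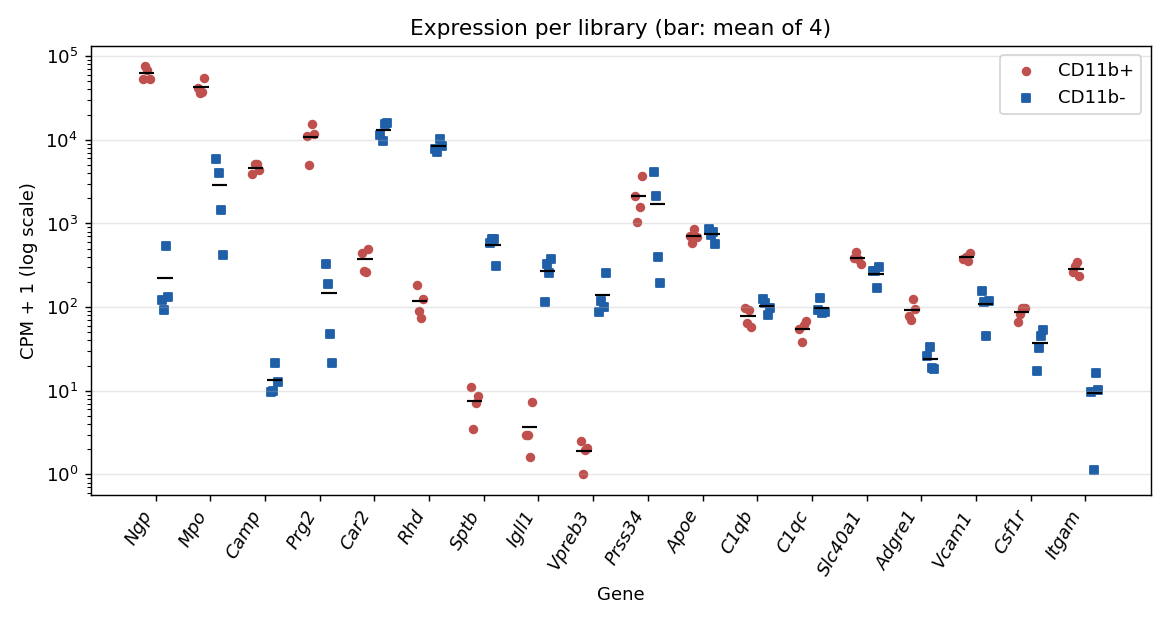
CPM + 1 on a log axis for 18 genes named in the text, with 1 point per library (circles, CD11b+; squares, CD11b-; 4 of each per gene) and a bar at the mean. Granule genes such as Ngp sit higher in CD11b+, erythroid and B cell genes such as Rhd and Igll1 higher in CD11b-, while Apoe lies in the same range in both, and Prss34 and Mpo spread widely among the CD11b- libraries.

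Genes of the sort were all higher in CD11b+, those of surface proteins that both gates required included. Itgam, which encodes CD11b, was at 287 ± 48.5 CPM in CD11b+ and 8.35 ± 6.24 CPM in CD11b-, a 34.8-fold difference (log2 5.12, SE 0.92, adjusted p = 0.00215). Adgre1, which encodes F4/80, was 4.10-fold higher in CD11b+ at 91.3 ± 23.8 against 23 ± 7.02 CPM (adjusted p = 0.00034), although both gates required the protein. Vcam1 was 3.84-fold higher at 394 ± 38.0 against 107 ± 46.4 CPM (adjusted p = 0.000826). Csf1r, the receptor whose promoter drives the reporter, was 2.42-fold higher in CD11b+ at 85.3 ± 15.2 against 36.0 ± 15.7 CPM (adjusted p = 0.0205), and this call was lost without CD11b- replicate 2, CD11b+ replicate 3 or CD11b+ replicate 4 (adjusted p from 0.0516 to 0.0529, and from 0.00326 to 0.0529 over all alternatives). Ptprc, the pan-leukocyte antigen CD45, was 1.68-fold higher at 253 ± 12.4 against 157 ± 34.4 CPM (adjusted p = 0.00422). Ly6g was not analysed here.

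Among the largest differences toward CD11b+ were those of Mogat2 and Dgat2, acyltransferases of triacylglycerol synthesis, and of Itgb2l, an integrin beta subunit. All 3 had no count in any CD11b- library. Against a floor of 3 counts over the pooled CD11b- libraries, Mogat2 (199 ± 37.3 CPM) was at least 8307-fold higher, Dgat2 (130 ± 20 CPM) at least 5376-fold and Itgb2l (86.9 ± 13.7 CPM) at least 3592-fold. Ear6, an eosinophil ribonuclease, had 3 pooled counts in CD11b- and a pooled ratio of 8236 (exact 95% counting interval 2818 to 39940). Dram1, a regulator of autophagy, and the inositol phosphatase Inpp5j had 2 each, with ratios of 4529 (1254 to 37403) and 4274 (1183 to 35295). The tight junction gene Cldn15 was 3364-fold higher at 172 ± 8.66 CPM, and all its CD11b- counts were in CD11b- replicate 1, without which it was at least 5446-fold higher. The heparan sulfate proteoglycan gene Gpc1 was 1743-fold higher at 99.5 ± 56.4 CPM. Without CD11b- replicate 2 it had 1 pooled count left in CD11b- and a pooled ratio of 8746 (1570 to 345469). Ear6 and Inpp5j likewise had their CD11b- counts in 1 library each, and were at least 5895-fold higher without CD11b- replicate 2 and at least 2100-fold higher without CD11b- replicate 3. Adjusted p for these 8 genes ran from 1.35e-06 to 1.85e-05.

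The largest differences toward CD11b- included erythroid and B cell precursor genes. Ackr1, the Duffy chemokine receptor of red cells, was at 293 ± 68.5 CPM in CD11b- and 1.79 ± 1.68 CPM in CD11b+, 160-fold lower (adjusted p = 0.000317; 268-fold without CD11b+ replicate 1). Redrum, a long noncoding RNA, was 113-fold lower at 1.18 ± 2.01 against 140 ± 23.3 CPM (adjusted p = 0.00455; 775-fold without CD11b+ replicate 2). Vpreb3 and Igll1, components associated with the pre-B cell receptor, were 151-fold and 96.5-fold lower (adjusted p = 0.000242 and 0.000111; Igll1 168-fold without CD11b+ replicate 4). Myl4, a myosin light chain, was 194-fold lower (adjusted p = 0.000701; 686-fold without CD11b+ replicate 1), and Slc2a4, the insulin-regulated glucose transporter, 110-fold lower (adjusted p = 0.00326; 658-fold without CD11b+ replicate 2). Sh3tc2 was 103-fold lower (adjusted p = 2.23e-06) and the butyrophilin-like gene Btnl10 was 91.8-fold lower (adjusted p = 1.57e-05).

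Next, 25 marker lists fixed before the data were examined were compared, of which 23 had at least 3 tested genes for camera, a test of whether the genes of a list shift relative to all other genes. With its preset correlation of 0.01 camera called 14 lists, 5 higher and 9 lower in CD11b+. None of the 14 calls held with a correlation estimated from these libraries, where camera called 0 lists, with 7 at an unadjusted p under 0.05, and fry, which tests a list by itself, called 19. The estimate was -0.0399 for plasmacytoid dendritic cell and -0.0342 for iron and heme handling genes, below the preset, and their calls were lost too. Called by fry but not by camera were resident macrophage, plasma cell, conventional dendritic cell and immediate early genes (lower) and lysosome genes (higher). Of the 35 splits of the 8 libraries into groups of 4, 6 gave at least as many called lists (15 at most), so that share does not exclude chance for the number of called lists. The 5 besides the real one keep 3 of the 4 libraries of each population together and so hold part of the real difference, and the 18 splits with 2 of each population on either side called 0 to 3 lists. The counts of single genes past the gene test, the levels per library and, for each list, the adjusted p with an estimated correlation are therefore given with each list. List members outside the naming rule are named where a count was 5 or fewer, where a list moved both ways or, in part, where an alternative ended a call. They were chosen after their values were seen. With 1 library left out in turn, the number of called genes ranged from 2 to 5 higher for monocytes, 3 to 6 lower for mature B cells, 3 to 6 lower for T cells, 0 to 1 higher and 2 to 4 lower for resident macrophages, and 0 to 1 higher and 0 to 2 lower for stem cells.

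Resident macrophage transcripts were detected in both populations. Of 18 tested members, 1 was higher, 3 were lower and 14 were not called in CD11b+ (the same 1 and 3 adjusted over the list alone), with camera adjusted p = 0.137, and 0.340 with an estimated correlation. Fry, which does not compare a list with other genes, called the list lower in CD11b+ (adjusted p = 0.0152). Apoe, an apolipoprotein that macrophages secrete, was at 708 ± 115 CPM in CD11b+ and 743 ± 125 CPM in CD11b- (log2 -0.03, 95% interval -0.43 to 0.37, adjusted p = 0.924). The iron exporter Slc40a1 was 1.60-fold higher in CD11b+ at 385 ± 52.0 against 249 ± 56.9 CPM (adjusted p = 0.0166, 0.0523 without CD11b+ replicate 2 and 0.0583 without the pair of CD11b- libraries highest in Mpo, from 0.00228 to 0.0583 over all alternatives). Lower in CD11b+ were the ficolin Fcna (3.22-fold, adjusted p = 0.0012), the heme oxygenase Hmox1 (2.19-fold, adjusted p = 0.00168) and the complement component C1qc (1.74-fold, 54.4 ± 13 against 97.5 ± 20.8 CPM, adjusted p = 0.0226). With each of the 8 libraries left out in turn, the C1qc call was lost in 3 cases (adjusted p from 0.0249 to 0.0665 over the 8). C1qa and C1qb were at 15.2 ± 4.18 and 77.2 ± 19.1 CPM in CD11b+ and at 26.7 ± 9.84 and 102 ± 19.6 CPM in CD11b-, neither called. The list shares 3 genes with other lists.

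Lysosome genes moved both ways: of 16 tested, 5 were higher, 3 lower and 8 not called (also 5 and 3 adjusted over the list alone), with camera adjusted p = 0.404, and 0.536 with an estimated correlation. Fry called this list higher in CD11b+ (adjusted p = 0.000629). Among those higher in CD11b+ were the hexosaminidase subunit Hexa (7.20-fold), the membrane proteins Lamp2 (6.50-fold) and Lamp1 (1.85-fold), and Grn (2.57-fold). Lower were the phosphatase Acp5 (8.91-fold), the protease Ctsb (2.44-fold, 1982 ± 87.1 against 4970 ± 393 CPM) and Lgmn (1.95-fold, a call lost with 5 of the 8 libraries left out in turn, adjusted p from 0.0155 to 0.112). The protease Ctsd was at 550 ± 86.5 and 614 ± 98.6 CPM (adjusted p = 0.683). Of 13 monocyte genes 5 were higher and 8 not called (6 higher adjusted over the list alone), with camera adjusted p = 0.0223, and 0.199 with an estimated correlation. The monocyte surface antigen gene Ly6c2 was 38.6-fold higher at 338 ± 72.8 against 8.93 ± 5.06 CPM (adjusted p = 7.59e-05), followed by F13a1 (28.9-fold, or 161-fold without CD11b- replicate 1), Tgfbi (17.3-fold, or 43.6-fold without CD11b- replicate 2), Ms4a6c (3.10-fold) and Csf1r. With each library left out in turn, the Tgfbi call was lost in 6 of 8 cases (adjusted p from 0.0157 to 0.0675) and the Ms4a6c call in 3 (0.0159 to 0.0533). Ly6c2 has a close paralog with which reads may be shared.

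Granulocyte lists showed the largest shifts toward CD11b+. All 9 genes placed on the primary granule list were higher (9 adjusted over the list alone), with a median 33.9-fold and camera adjusted p = 3.27e-06, and 0.113 with an estimated correlation. Among them Mpo was 15.2-fold higher (adjusted p = 0.00187), the elastase Elane 66.1-fold (adjusted p = 0.000481; 122-fold without CD11b- replicate 1) and the haptoglobin Hp 124-fold (adjusted p = 2.38e-05; 214-fold without CD11b- replicate 3). Of 16 neutrophil genes 12 were higher and 4 not called (12 adjusted over the list alone), with a median of 129-fold and camera adjusted p = 1.94e-07, and 0.113 with an estimated correlation. Ngp was 283-fold higher (adjusted p = 3.5e-05; 581-fold without CD11b- replicate 3), the antimicrobial peptide gene Camp 376-fold (4623 ± 625 against 12.5 ± 5.45 CPM, adjusted p = 1.39e-06) and the neutrophil surface protein Cd177 584-fold (adjusted p = 7.47e-05). Of 10 eosinophil genes 7 were higher and 3 not called (9 higher and 1 lower adjusted over the list alone), with a median of 69.7-fold and camera adjusted p = 0.000246, and 0.137 with an estimated correlation. The granule protein genes Prg2 (10797 ± 4256 against 147 ± 144 CPM) and Epx (1988 ± 567 against 33.3 ± 35.1 CPM) were 77.0-fold and 63.2-fold higher (adjusted p = 0.000518 and 0.00766), and 129-fold and 99.2-fold without CD11b- replicate 1. Counts of the related Ear genes are uncertain, since near-identical copies may share reads.

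Basophil and mast cell genes did not pass as a list. Of 8 tested, the histidine decarboxylase Hdc was called higher (13.9-fold, adjusted p = 0.000456) and 7 were not called (1 higher adjusted over the list alone), with camera adjusted p = 0.376, and 0.695 with an estimated correlation. The protease Prss34 was at 2109 ± 1138 CPM in CD11b+ and 1709 ± 1820 CPM in CD11b- (adjusted p = 0.786). Its 4 CD11b- libraries stood at 4105, 2139, 399 and 193 CPM, and the same libraries had 5827, 3966, 1457 and 413 CPM of Mpo. Leaving out the pair of CD11b- libraries highest in Mpo, chosen after the data were examined, Prss34 (adjusted p = 0.0103, from 0.0103 to 0.996 over all alternatives) and the list (adjusted p = 0.00381, from 0.00381 to 0.695 over all alternatives) were called higher in CD11b+. Without that pair 3305 genes were called, 2853 of them among the 3549, and 4 basophil and mast cell genes. Without it Mpo was 44.9-fold higher, Elane 276-fold, Prg2 320-fold, Epx 617-fold, Hdc 37.0-fold, F13a1 590-fold, Tgfbi 31.3-fold and Ngp 186-fold. The pooled ratio without it was 5927 (1064 to 234124) for Gpc1 and 2073 (574 to 17120) for Inpp5j, with 1 and 2 counts, and the bounds were at least 3995-fold for Ear6, 3434-fold for Cldn15 and 1465-fold for Dram1, which had none. The calls of C1qc, Cr2, Cd3g and Angpt1 were lost without it (adjusted p = 0.126, 0.0911, 0.0879 and 0.316). So were those of the plasmacytoid dendritic cell gene Spib, the cell cycle gene Bub1 and the interferon response gene Oasl2 (edgeR adjusted p = 0.0882, 0.191 and 0.0607).

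Erythroid genes were lower in CD11b+ throughout. All 15 tested members were lower (15 adjusted over the list alone), with a median 40.0-fold difference and camera adjusted p = 4.52e-13, and 0.0533 with an estimated correlation. Car2 was 34.4-fold lower (adjusted p = 4.11e-06), the blood group antigen gene Rhd 69.6-fold lower at 117 ± 48.1 against 8333 ± 1333 CPM (adjusted p = 3.11e-06) and the membrane skeleton gene Sptb 81.2-fold lower at 6.59 ± 3.17 against 546 ± 163 CPM (adjusted p = 1.18e-05). The globin genes and 2 further members of this list were not analysed here. Of 23 cell cycle genes 21 were lower and 2 not called (21 adjusted over the list alone), with a median 2.53-fold difference and camera adjusted p = 1.01e-10, and 0.0533 with an estimated correlation. The ubiquitin-conjugating enzyme of mitosis Ube2c was 6.39-fold lower (adjusted p = 1.01e-05), the ribonucleotide reductase subunit Rrm2 3.35-fold lower at 1589 ± 69.4 against 5485 ± 861 CPM (adjusted p = 2.76e-05) and the replication factor Mcm6 1.67-fold lower (adjusted p = 0.00322). Of 13 iron and heme handling genes 8 were lower, 4 not called and Slc40a1 higher (9 lower and 1 higher adjusted over the list alone), with a median 2.19-fold difference and camera adjusted p = 0.000331, and 0.0533 with an estimated correlation. The biliverdin reductase Blvrb was 28.1-fold lower at 51.0 ± 11.4 against 1472 ± 149 CPM (adjusted p = 1.35e-06), and the ferritin genes Fth1 and Ftl1, which have pseudogene copies that may share reads, were 7.14-fold and 2.36-fold lower (adjusted p = 1.3e-05 and 0.000236).

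B cell genes were lower in CD11b+. Of 12 B progenitor genes 11 were lower and Rag2 was not called (11 lower adjusted over the list alone), with a median log2 change of -5.78, which stayed at -5.78 with Vpreb2 at its bound, and camera adjusted p = 1.04e-07, and 0.113 with an estimated correlation. The signalling chain gene Cd79b was 4.58-fold lower at 59.6 ± 20.9 against 283 ± 105 CPM (adjusted p = 0.000492) and Vpreb2, with no count in any CD11b+ library, at least 379-fold lower (adjusted p = 0.00107). Vpreb1 and Vpreb2 are near-identical, so the split of their reads is uncertain. Of 8 mature B cell genes 5 were lower and 3 not called (7 lower adjusted over the list alone), with camera adjusted p = 0.00139, and 0.139 with an estimated correlation. Those 5 were Cd22 (32.4-fold, adjusted p = 0.034), Fcrl1 (6.54-fold), Bank1 (4.07-fold), Fcrla (11.3-fold) and Cr2 (16.5-fold, or 26.1-fold without CD11b+ replicate 1). The Cr2 call was lost in 6 of 8 cases with 1 library left out (adjusted p from 0.0348 to 0.113). Without CD11b+ replicate 3, which held most of the CD11b+ counts of Cd22, that gene was 479-fold lower. Its call was lost without CD11b+ replicate 1 or 4 or CD11b- replicate 1, 3 or 4 or without the pair of CD11b- libraries highest in Mpo (adjusted p from 0.0546 to 0.0815, and from 3.06e-05 to 0.0815 over all alternatives). Of 7 plasma cell genes 4 were lower, 2 not called and the transcription factor Xbp1 2.27-fold higher (4 lower and 1 higher adjusted over the list alone), with camera adjusted p = 0.204, and 0.340 with an estimated correlation. The lower 4 were Jchain (6.56-fold), Sdc1 (6.60-fold, or 3.22-fold without CD11b- replicate 3), Mzb1 (22.5-fold) and Irf4 (69.8-fold, or 153-fold without CD11b+ replicate 4). The Sdc1 call was lost with 4 of the 8 libraries left out in turn (adjusted p from 0.0092 to 0.0658). The Xbp1 call was lost without the pair of CD11b- libraries highest in Mpo (adjusted p = 0.0900, from 0.000285 to 0.0900 over all alternatives).

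Of the T, NK and dendritic cell lists, members that were called were lower in CD11b+. Of 9 T cell genes 4 were lower and 5 not called (4 lower adjusted over the list alone), namely the kinase Lck (7.20-fold, 21.4 ± 14.2 against 158 ± 32.9 CPM), Tcf7 (5.23-fold), Cd3d (30.4-fold) and Cd3g (23.7-fold, or 62.4-fold without CD11b+ replicate 4). With 5 of the 8 libraries left out in turn the Cd3g call was lost (adjusted p from 0.0285 to 0.0952). Camera gave adjusted p = 0.00184, and 0.139 with an estimated correlation. Where the filter was a CPM of 10 in 4 libraries the T cell call was lost (adjusted p = 0.0798, from 0.000206 to 0.139 over all alternatives). Of 9 NK cell genes 2 were lower and 7 not called (2 lower adjusted over the list alone), Klrb1c (4.21-fold) and the cytokine receptor subunit Il2rb (9.02-fold, or 15-fold without CD11b+ replicate 3), while Gzma stood at 10.2 ± 6.85 and 8.85 ± 5.19 CPM. For NK cells camera gave adjusted p = 0.029, and 0.272 with an estimated correlation, and the call was lost without CD11b- replicate 1, 2 or 3 or CD11b+ replicate 1 (adjusted p from 0.0868 to 0.147) and without the pair of CD11b- libraries highest in Mpo (adjusted p = 0.201), with a range from 0.00976 to 0.272 over all alternatives. The Klrb1c call was lost, at 2.70-fold lower, without the pair of CD11b- libraries highest in Mpo (adjusted p = 0.0700, from 1.48e-05 to 0.0700 over all alternatives). Of 10 plasmacytoid dendritic cell genes 8 were lower and 2 not called (8 lower adjusted over the list alone), with a median log2 change of -3.53, the same with its 2 all-zero genes at their bounds, and camera adjusted p = 2.95e-05, and 0.0533 with an estimated correlation. With the replicate number as a block the calls of Tcf4, Klk1 and Spib among these 8 were lost (edgeR adjusted p = 0.0603, 0.0727 and 0.0595). The Spib call was also lost with 5 of the 8 libraries left out in turn (adjusted p from 0.00142 to 0.0778). The interferon regulatory factor Irf7 was 10-fold lower at 34.6 ± 7.55 against 355 ± 88.4 CPM (adjusted p = 1.61e-05), Irf8 4.03-fold lower (adjusted p = 0.00906), and the chemokine receptor Ccr9, at 0 in all CD11b+ libraries, at least 726-fold lower, or at least 368-fold without CD11b- replicate 2. Of 6 conventional dendritic cell genes 2 were lower and 4 not called (2 lower adjusted over the list alone), Ccr7 (12.6-fold) and Zbtb46 (27.6-fold, or 42.6-fold without CD11b+ replicate 4), with camera adjusted p = 0.402, and 0.536 with an estimated correlation. Cd209a was at 32.4 ± 16.3 and 27.1 ± 9.19 CPM.

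Interferon response genes were lower in CD11b+ in part. Of 12 tested, 7 were lower and 5 not called (8 lower and 1 higher adjusted over the list alone), with a median 4.16-fold difference and camera adjusted p = 0.00077, and 0.137 with an estimated correlation. The antiviral genes Ifit1 and Rsad2 were 23.4-fold and 15.5-fold lower (adjusted p = 2.47e-05 and 2.23e-06). Irf7 stands in this list as well. Of 9 immediate early genes 2 were lower, 1 higher and 6 not called (the same adjusted over the list alone). Dusp1 and Btg2 were 12.0-fold and 9.72-fold lower and Ier2 was 4.45-fold higher. The list's mean log2 change was -0.59, its median 0.00 and camera's direction lower (adjusted p = 0.587, and 0.636 with an estimated correlation). Of 16 secretory genes of the endoplasmic reticulum 7 were higher, 8 not called and the stress-induced transcription factor Ddit3 7.82-fold lower (11 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.0139, and 0.317 with an estimated correlation. The chaperone cofactor Sdf2l1 was 2.93-fold higher (adjusted p = 0.000151). The translocon-associated Ssr1 was at 2956 ± 701 and 1740 ± 673 CPM (adjusted p = 0.0594), and was called in 8 alternatives, among them without CD11b- replicate 1 (adjusted p = 0.0356, from 0.00952 to 0.151 over all alternatives). Hspa5 was at 1742 ± 389 and 1629 ± 105 CPM.

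The remaining lists showed few calls. Of 7 megakaryocyte and platelet genes Gp9 was 32.1-fold lower and 6 were not called (1 lower adjusted over the list alone). The mean log2 change was -0.35, against a median of 0.13 and an upward camera direction (adjusted p = 0.751, and 0.808 with an estimated correlation). Itga2b was at 30.4 ± 9.08 and 15.3 ± 7.46 CPM, called without the pair of CD11b- libraries highest in Mpo (adjusted p = 0.0271, from 0.0271 to 0.224 over all alternatives), and Pf4 at 22.3 ± 12.6 and 19.9 ± 15.7 CPM. Of 8 stem and progenitor genes the receptor Kit was 2.56-fold higher, Angpt1 2.61-fold lower and 6 not called (1 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.402, and 0.622 with an estimated correlation. The Kit call (adjusted p = 0.0393) was lost without any one of the 4 CD11b+ libraries, CD11b- replicate 2, CD11b- replicate 3 or the pair of CD11b- libraries highest in Mpo (adjusted p from 0.0502 to 0.0915, and from 0.00411 to 0.0915 over all alternatives). The Angpt1 call was lost with 6 of the 8 libraries left out in turn (adjusted p from 0.0139 to 0.116). Cd34 was at 51.9 ± 26.7 and 83.3 ± 65.1 CPM. No endothelial gene of 3 tested was called by edgeR, against 1 at an unadjusted p under 0.05 and 1 called by DESeq2 (0 adjusted over the list alone; camera adjusted p = 0.402, and 0.536 with an estimated correlation). Vwf was at 2.21 ± 2.79 and 20.3 ± 4.02 CPM (adjusted p = 0.0589) and was called in 8 alternatives, among them without CD11b+ replicate 1 or 3 (adjusted p = 0.0201 and 0.0408, from 0.000378 to 0.135 over all alternatives). Pecam1 was at 36.6 ± 12.6 and 39.4 ± 11.55 CPM. Only 2 MHC class II genes and 2 stromal genes were tested, too few for camera. Of these Cd74 was 2.13-fold lower in CD11b+ (adjusted p = 0.0217; 0.0516 without CD11b- replicate 4 and 0.0582 without CD11b+ replicate 2, from 0.00107 to 0.0582 over all alternatives), and Ciita was not called (1 lower adjusted over the list alone). The stromal genes Cxcl12 and Kitl were at 3.54 and 2.41 CPM in CD11b+ and at 9.0 and 11 CPM in CD11b-, with 0 called by edgeR, 0 by DESeq2, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Cxcl12 was called by limma with a pseudocount of 5 (adjusted p = 0.0476, from 0.0476 to 0.659 over all alternatives).

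Within each population, levels of the lists were set against all detected genes. The median macrophage-list member stood at the 41.9 ± 7.49 percentile of detected genes in CD11b+ and at 52.0 ± 2.48 in CD11b- (SD, n = 4). The neutrophil list stood at 96.8 ± 0.694 and 35.7 ± 11.5, the primary granule list at 99.5 ± 0.0974 and 54.2 ± 8.78, the erythroid list at 64.7 ± 5.52 and 99.3 ± 0.157, and the B progenitor list at 13.3 ± 6.16 and 75.7 ± 10.3. Among genes at a CPM of at least 1 the B progenitor list stood at 1.19 in CD11b+ and the neutrophil list at 22.6 in CD11b-. Cell cycle genes were among the most abundant in both, at 96.0 ± 0.361 and 98.5 ± 0.169. The list mean of log2(CPM + 1) differed for 18 of 25 lists, 5 higher and 13 lower in CD11b+, by an exact permutation test of both directions over 70 splits (adjusted p = 0.0397 for each of the 18). Their p of 0.0286 is the smallest this design can give, so the test does not rank these lists. The 5 higher were the neutrophil, eosinophil, primary granule, monocyte and lysosome lists. The macrophage list mean was 3.62 ± 0.0423 in CD11b+ and 4.23 ± 0.258 in CD11b-, one of the 13 lower. The lists whose levels were not called were those of basophils and mast cells, megakaryocytes, conventional dendritic cells, MHC class II, stem cells, stroma and endoplasmic reticulum secretion. CPM is not corrected for transcript length, so percentiles compare molecules of different length only loosely.

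**Figure D2:**
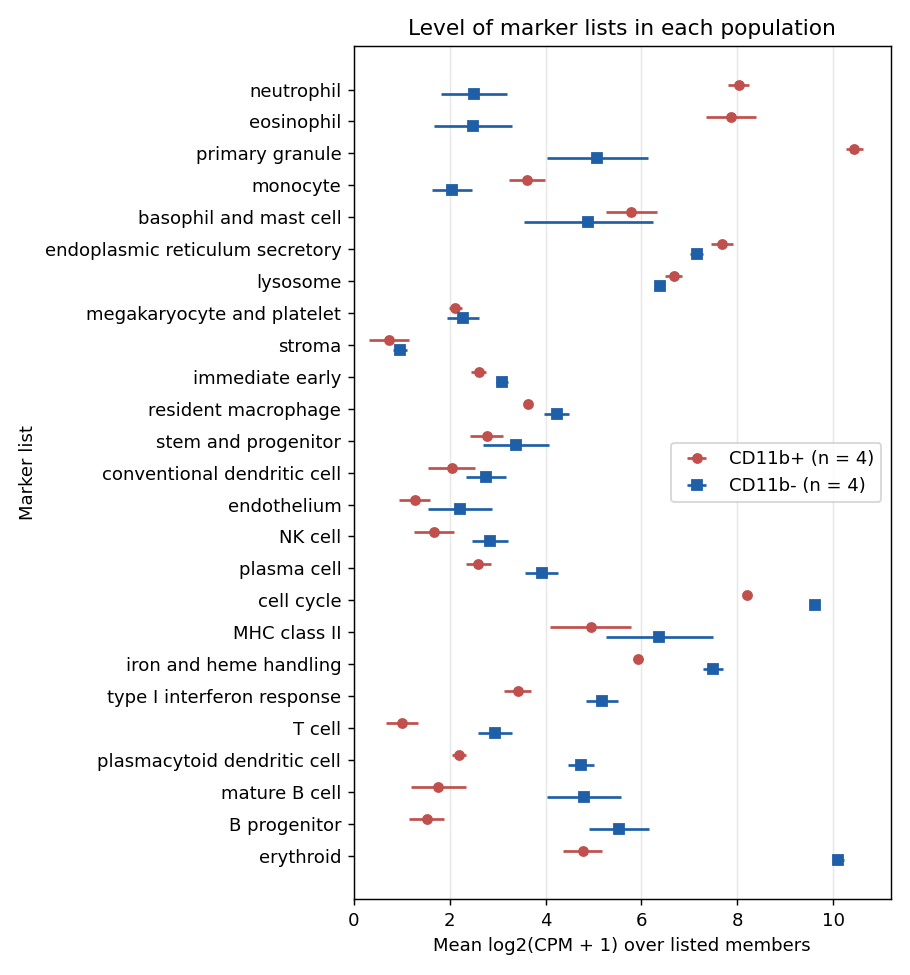
Mean log2(CPM + 1) over the listed members of each of 25 marker lists (x axis) for CD11b+ (circles) and CD11b- (squares). Points are means of 4 libraries and bars are SD. The erythroid list lies at 4.77 in CD11b+ and 10.1 in CD11b-, the neutrophil list at 8.03 and 2.51, and the resident macrophage list at 3.62 and 4.23.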

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

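Of 213 sets of 4 libraries examined (named genes, list levels, library totals and the share of the 10 most abundant genes, in each population, where the 4 values were not all equal), 13 held a library that lay far from the other 3, with a gap to its nearest neighbour beyond Dixon's 95% critical share of the range. Chance gives about 1 in 20 sets, or 10.6 here, if sets are independent and values normally distributed. These sets share libraries, and a set with counts in only 1 library always passes. The 13 against 10.6 therefore cannot show whether chance accounts for them. The permutation test at the end of this part was chosen after the data were examined.

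In CD11b- the stray values were those of replicate 3 for Ngp at 535 CPM (others 90.6 to 133), Btnl10 at 181 CPM (91.5 to 106), Cxcl12 at 9.61 CPM (8.74 to 8.87) and the conventional dendritic cell list level at 2.13 (2.89 to 3.0). Ngp did not stand alone there. The median of the 12 called neutrophil-list genes was 1.01% of its CD11b+ level in replicate 3. It was 0.192%, 0.117% and 0.312% in replicates 1, 2 and 4. CD11b- replicates 1, 2 and 3 held the sole counts of Cldn15 (0.211 CPM), Ear6 (0.0857 CPM) and Inpp5j (0.0618 CPM), where the other libraries were at 0. In CD11b+, replicate 2 stood apart for Redrum at 4.16 CPM (0 to 0.548), Slc2a4 at 1.83 CPM (0 to 0.209), Xbp1 at 419 CPM (546 to 563) and the share of counts in the 10 most abundant genes at 19.2% (18.3% to 18.5%). CD11b+ replicate 1 stood apart for Myl4 at 0.931 CPM (0 to 0.13) and CD11b+ replicate 3 for Cd22 at 5.39 CPM (0 to 0.246).

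A signal outside the comparisons lies in the rows whose names are numbers. The most abundant of them, named 37316, had 1574 ± 209 CPM in CD11b- and 205 ± 14.8 CPM in CD11b+ (SD, n = 4; exact permutation p = 0.0286, the smallest possible), where a count of 0 allows at most 0.109 CPM. 2 rows bear this name, and which gene stands behind either was not determined.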

How the results depend on the processing

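Settings added after seeing the data were limma on log2(CPM + 1), both unscaled fits, length-scaled counts and the fits without the pair of CD11b- libraries highest in Mpo. The count of called genes, 3549, stayed within 2843 (at least 2-fold) and 4578 (limma with a pseudocount of 5) in all alternatives, with 4247 by DESeq2, 3545 of them shared, and 3035 to 3418 when 1 library was left out. It was 3511 (1923 higher, 1588 lower) unscaled without the 20 most abundant genes, where the median log2 change of all genes was 0.0925, against -0.01 in the main test. Of 35 splits of the 8 libraries only 1, the real one, reached 3549 called genes, which is the smallest share this design can give. The other splits gave at most 0 called genes. They mix the populations, which widens the spread within groups, so the contrast of 0 with 3549 does not measure chance. For the 14 called lists the share of splits, 6 of 35 with up to 15 lists, does not exclude chance, but the 5 besides the real one keep 3 of 4 libraries of each population together, and the 18 with 2 of each on either side called at most 3. Called lists numbered 0 with an estimated correlation (the cause was not tested), 19 with fry, which does not compare a list with other genes, and 13 to 14 with 1 library left out. Estimates below the preset, at -0.0399 for plasmacytoid dendritic cell and -0.0342 for iron and heme handling genes, came with lost calls as well. These values argue against correlation within those lists as the cause of their losses. Levels were called for 15 to 18 lists, and 8 median percentiles moved by more than 1 SD: among genes at a CPM of at least 1, B progenitor (1.19), erythroid (57.4) and macrophage (30.0) in CD11b+ and neutrophil (22.6) and macrophage (42.2) in CD11b-, and with length-scaled counts erythroid (74.4) and neutrophil (97.9) in CD11b+ and macrophage (59.4) in CD11b-. Folds moved by over 1.5 times for 28 of 65 called genes under the naming rule with a limma pseudocount of 5, and for 18 with 0.1. At this depth a count of 0 does not exclude a level of up to about 0.11 CPM in a library. Of 65 called genes under the naming rule 58 kept direction and call in every alternative and 7 lost the call in at least 1. Of 15 uncalled, 10 stayed so.

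Among genes under the naming rule and lists, changes of sign were seen only in ones that were not called, and none became called with the opposite sign. The cause was not tested. Without the Mpo-rich pair the log2 change was 0.0579 for Apoe, 0.48 for Cd34, 0.0158 for Ctsd and 0.30 for Pecam1. Unscaled without the 20 most abundant genes it was 0.0774 for Apoe and 0.0388 for Pecam1. With 1 library left out Apoe ranged from -0.13 to 0.0595, Cd209a from -0.0594 to 0.55, Gzma from -0.13 to 0.74, Pecam1 from -0.23 to 0.12, Pf4 from -0.15 to 0.72 and Prss34 from -0.0156 to 1.25. The megakaryocyte list had a signed -log10 p of -0.0355 with a CPM minimum of 10, and between -0.0726 and 0.164 with 1 library left out.

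Whether replicate numbers pair the libraries is not stated in the labels. The correlations of deviations between same-numbered libraries were 0.00448, 0.00440, 0.00225 and 0.0430, and not every library correlated best with its own number. These values do not show a pairing, but low correlations between different populations cannot exclude it. With the replicate block 3195 genes were called, 3047 of them shared with the main test, and 14 lists. The block moved 6 of the 65 folds by over 1.5 times, Cd22 most (log2 -7.96). It ended the calls of C1qc, Ms4a6c, Cr2, Sdc1, Angpt1, Tcf4, Klk1 and Spib, list members outside the naming rule. Alternatives on FPKM, and edgeR on reads recovered from CPM, were not run.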

Other observations

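All tests in this part were chosen after the results they bear on had been seen, and the gene families were chosen after the data had been examined. Among genes of heme synthesis, Alas2 of the erythroid list was 18.8-fold lower in CD11b+. Ferrochelatase, Fech, which inserts iron into heme, was at 733 ± 71.5 CPM in CD11b+ and 14203 ± 1168 CPM in CD11b- (SD, n = 4; edgeR adjusted p = 1.35e-06). Cpox was 36.3-fold lower at 34.0 ± 12.3 against 1263 ± 53.7 CPM (edgeR adjusted p = 2.75e-06), and Alad 31.0-fold lower at 75.9 ± 23.2 against 2413 ± 325 CPM (edgeR adjusted p = 2.66e-06).

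Of 38 proteasome subunits 13 were lower and 1 higher, with a median log2 change of -0.33 (camera adjusted p = 0.0232, and 0.561 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 2 were lower (median log2 change -0.19, camera adjusted p = 0.0328, and 0.764 with an estimated correlation). These medians were -0.22 and -0.08 with no scaling and totals without the 20 most abundant genes, which left 8 proteasome subunits lower and 1 higher and 1 cytosolic ribosomal gene lower, and moved the median of all genes from -0.01 to 0.09. With 1 library left out in turn 8 to 13 proteasome subunits were lower and 0 to 1 higher, and 1 to 4 cytosolic ribosomal genes lower; without the pair of CD11b- libraries highest in Mpo 7 subunits were lower. The vacuolar ATPase subunits, which acidify lysosomes, had 8 higher (5 to 8 with 1 library left out) and 1 lower of 17 (median log2 change 0.43, camera adjusted p = 0.157, and 0.491 with an estimated correlation). Of 74 mitochondrial ribosomal protein genes 8 were higher and 6 lower (camera adjusted p = 0.711, and 0.954 with an estimated correlation), against 8 and 2 with those totals, where their median log2 change turned from -0.10 to 0.0016, and 6 to 9 higher and 2 to 5 lower with 1 library left out. Of 91 respiratory chain and ATP synthase genes 8 were higher and 13 lower (camera adjusted p = 0.157, and 0.848 with an estimated correlation), against 12 and 7 with those totals, 5 to 8 and 6 to 11 with 1 library left out, and 4 and 9 without that pair. Of 32 ubiquitin-conjugating enzymes 2 were higher and 10 lower (camera adjusted p = 0.151, and 0.491 with an estimated correlation). Of 18 autophagy genes 4 were higher and 4 lower (camera adjusted p = 0.956, and 0.954 with an estimated correlation), and their median turned from -0.03 to 0.08 with those totals.

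Of the 14 called lists, 8 had a smaller camera p in the real split than in every other split, namely primary granule, neutrophil, eosinophil, erythroid, B progenitor, plasmacytoid dendritic cell, cell cycle and iron and heme handling. Of the other splits 16 keep 3 of the 4 libraries of each population together and so hold part of the real difference. For the other 6 lists at least 1 other split gave a p as small: type I interferon response (2 of 35 splits, the real one included), T cell (5), endoplasmic reticulum secretory (5), mature B cell (6), monocyte (8) and NK cell (11). Of these splits only 2 for monocyte and 2 for NK cell held 2 libraries of each population on either side.

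The CD11b- libraries held 413 to 5827 CPM of Mpo. Carry-over of CD11b+ cells or their RNA as a whole is argued against: in CD11b- replicates 1 to 4 Mpo stood at 13.7%, 9.34%, 3.43% and 0.973% of its CD11b+ mean, while the median of all 16 neutrophil-list genes stood at 0.192%, 0.169%, 1.01% and 0.374%, and that of the 12 called ones at 0.192%, 0.117%, 1.01% and 0.312%. The primary granule list, which holds Mpo, lay nearer the Mpo share in each library (median 5.05%, 3.48%, 2.07% and 0.444%), as did the eosinophil list in all but replicate 3 (2.15%, 2.28%, 0.422% and 0.629%), and 2, 2, 4 and 6 of the 16 neutrophil genes lay above it, among them the 4 uncalled ones in some libraries, at 2.40 to 17.6 CPM in CD11b+. Another candidate source, a hypothesis, is progenitors with basophil or mast cell transcripts, which may pass a gate without CD11b. The median of the 8 basophil and mast cell genes stood at 206%, 106%, 29.0% and 19.7% of CD11b+, with Prss34 at 193 to 4105 CPM, but 4 libraries cannot decide this, and carry-over of CD11b+ cells rich in Mpo and poor in neutrophil genes stays open as well.

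Macrophage-list genes differed by amounts usual for genes of their level: the list's median absolute log2 change of 0.72 lay at percentile 24.65 of 10000 lists matched on mean level, whose median was 0.89. One shared source with a fixed ratio of its transcripts, such as macrophage fragments of one kind in both sorts, may be considered as a hypothesis. For the 12 members at 10 CPM or more it is argued against as the only source of them all, because Slc40a1 was called higher in CD11b+ and Fcna, Hmox1 and C1qc lower. Their differences between populations spread more than in other splits (SD 0.94 on the log2 scale, exact permutation p = 0.0286, the smallest possible). Those calls came from the same libraries, so the spread adds no separate support. The Slc40a1 call, the sole one toward CD11b+, was lost without CD11b+ replicate 2 (edgeR adjusted p = 0.0523) and without the Mpo-rich pair (0.0583). The C1qc call was lost with 3 of the 8 libraries left out in turn, without that pair (0.126) and with the replicate block (0.0745). Fcna and Hmox1 kept their calls in all these fits. A shared source beside expression by other cells, or for a part of the list, stays open. For C1qa, C1qb and C1qc alone a fixed ratio and different ratios cannot be told apart (exact permutation p = 0.343 over 3 genes). Their summed level was 147 ± 25.4 CPM in CD11b+ and 227 ± 42.7 CPM in CD11b-, a ratio of 1.54 (SD, n = 4; exact permutation p = 0.0286).

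A few abundant transcripts that take up CD11b+ counts could lower all other genes there. With totals that leave out the 20 most abundant genes and no scaling, 1588 of the 1798 genes lower in CD11b+ were still called lower. Of the others 200 lost that call and 10 were among the 20 genes left out, which were thus not only genes abundant in CD11b+. The median log2 change of all genes moved from -0.01 in the main test to 0.0925, while 1403 called genes were at least 2-fold lower. A shift of that size could hardly end most calls, so the number kept adds little. Its size argues against these 20 genes as the whole cause.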
